A study of Ricinus communis with 18 samples.

How the data were processed

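The deposited table lists 21332 genes with 2 columns for each of the 18 libraries. The file headers name them as counts and FPKM. The deposited values of the first kind hold some fractions and are expected counts, that is estimates of reads per gene; at least 98.3% of the values of every library were whole numbers. They were rounded and used for all tests. FPKM, the unit the authors give for the other columns, served for levels. Per the labels, the description and the title of untreated libraries of day 11 point to different FPKM columns, so the 3 FPKM columns of that group, of 36 per-sample columns, were left out. FPKM of that group was computed here from the counts, the library totals and the gene lengths implied by the usable columns. Levels of the other groups are the deposited FPKM. Computed and deposited values of the other libraries had ratios between 0.994 and 1.01 (5% and 95% quantiles). Gene lengths were available for 16073 of the tested genes.

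Per the labels, RNA was extracted with Trizol from root systems and libraries were made with a kit that selects mRNA. The read aligner, the counting tool and the genome build are not given in the sources used here. Of the gene identifiers, 20538 carry an NCBI gene number and 794 an assembled-locus number. A reference table with names only held 18929 of them, and no coordinates were available. Gene products are the best hits in other species that the authors list, mostly from Jatropha curcas, so a product name is that of a related protein. Reads shared between paralogs, such as copies of zeaxanthin epoxidase or nicotianamine synthase, may be split between them in ways that cannot be seen here, and values of single copies are uncertain.

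Library totals ran from 6607760 to 10817476 counts. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which kept 16085 genes or 75.4%. Libraries were scaled by TMM, and all 18 were fitted with 1 mean per group by edgeR's quasi-likelihood test with robust dispersion (R 4.3.3, edgeR 4.0.16). P-values were adjusted by Benjamini and Hochberg within each of 7 comparisons, and genes with an adjusted p below 0.05 were called, with the number at 2-fold or more given beside. The comparisons were PEG at 3 days, PEG at 7 days and rehydration at 11 days, each against controls of the same day, 2 interactions between them, and controls of 7 and 11 days against those of 3 days. TMM factors were 0.765 to 0.806 in PEG roots at 3 days and 0.968 to 1.267 in untreated roots, so the choice of scaling matters for the balance of higher and lower genes.

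The 41 gene lists were set up by product name, and the groups, the tests, the lists and a first set of alternatives were chosen before the data were examined. Lists with at least 3 tested genes were tested by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 41 lists, and again with an estimated correlation. KEGG terms of 10 to 300 genes were tested in the same way. Genes were named by rule. The rule took the 8 largest increases and 8 largest decreases among called genes with a mean FPKM of at least 5 in a compared group, no overlap between the libraries compared and a described product, and up to 2 of each direction per list. For interactions it took 5 of each. Genes of some further families were looked at after their values were seen and are marked so.

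Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, limma on log2 FPKM with an offset of 1 or 0.1 (genes with FPKM of at least 1 in 3 libraries), only the libraries compared, replicate number as a block, an adjusted p below 0.01, and each library left out in turn. Scaling by library totals alone, removal of the gene length trend (a lowess curve with span 0.3 per library, prior count 2), DESeq2 size factors for the list tests and the LEA list without GEM-like proteins were added after seeing the data. Group labels were also exchanged, over 10 splits of the 6 libraries of a comparison and 100 of 200 possible regroupings for interactions. Simulated data were made from the means and dispersions of all 18 libraries, with changes put into well-counted genes of the 3-day PEG group. There edgeR recovered 75 of 100 genes changed 4-fold and 7 of 100 changed 2-fold, with 0 of 15885 unchanged genes called. DESeq2 recovered 92 and 20 with 17 false calls. A made-up length trend gave edgeR 94 false calls, and 2 after its removal. In this simulation, where few genes changed, 2-fold changes were thus often missed with 3 libraries per group. The share missed may differ in the real comparison at 3 days, where 3712 genes were called.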

Results

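RNA was sequenced from whole root systems of castor (Ricinus communis) kept untreated or given 15% PEG-6000, a polymer that holds back water and so imposes osmotic stress without entering the cells. Untreated and PEG-treated roots were taken at 3 and 7 days. A last pair of groups was taken at 11 days, when the treated roots had been without PEG for 4 days and are called rehydrated here. Each of the 6 groups held 3 libraries, 18 in all, and each time had its own untreated group. Total counts ran from 6607760 to 10817476 per library over 21332 genes, of which 16085 had enough counts to be tested. Each library was distinct from the others of its group beyond counting noise. Nothing says that the 3 libraries of a group came from separate plants, so the p-values measure the spread between these samples, which may be technical. The title of the series names the response to oxidative stress under drought as its subject, so the enzymes that remove reactive oxygen are given first at each time. Levels are mean FPKM ± SD of 3 libraries, and fold changes are log2 values ± SE, with the log2 values from edgeR's quasi-likelihood fit. The SE was computed here as the absolute log2 value over the square root of the F statistic. It is approximate, above all for genes with few counts in a group.

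After 3 days in PEG, 19 of 52 nutrient transporters were lower than in untreated castor roots and 2 higher. Of 68 pectin-modifying enzymes 13 were lower and 3 higher, and of 31 enzymes that remove reactive oxygen 6 were higher and 2 lower. The high-affinity nitrate transporter 2.1-like gene (ncbi_8275209) fell from 42.2 ± 22.7 to 0.413 ± 0.379 FPKM, a log2 change of -6.24 ± 0.64. An alpha-amylase/subtilisin inhibitor-like gene (ncbi_8276905), of a family of seed and stress proteins that block starch and protein breakdown, rose from 0.697 ± 0.92 to 64.4 ± 22.3 FPKM (6.97 ± 1.00). Across the 16085 genes tested, 1883 were higher and 1829 lower at an edgeR adjusted p below 0.05, and 2932 of them changed at least 2-fold. The genes called were 23.1% of those tested, so a family with about that share called is not set apart by its count. That holds for the pectin-modifying enzymes and the enzymes that remove reactive oxygen. Class III peroxidases, aquaporins and cytosolic ribosomal proteins, given below, had a smaller share called. The largest increases, with all 3 PEG libraries above all 3 controls, also took in a zinc finger family protein (ncbi_8269145, 5.88 ± 1.04), a second copy of the inhibitor (ncbi_8276906, 5.85 ± 0.95) and a cinnamyl-alcohol dehydrogenase family protein (ncbi_8260964, 5.70 ± 0.64). A 17.3 kDa class I heat shock protein (XLOC_012223) rose by 5.50 ± 1.15. They further held a secoisolariciresinol dehydrogenase-like gene (ncbi_8286003, 5.07 ± 0.79), the growth-restraining transcription factor IBH1-like (ncbi_8274777, 5.02 ± 0.76) and the exporter pleiotropic drug resistance protein 1-like (ncbi_8280248, 5.01 ± 1.29). The largest decreases were those of the nitrate transporter, a pectinesterase-like gene (ncbi_107260759, -5.88 ± 1.09), a WAT1-related transporter (ncbi_8262017, -5.77 ± 0.78) and the pectin-cleaving enzyme polygalacturonase (ncbi_8282586, -5.54 ± 0.87). They were followed by a pair of nicotianamine synthase-like genes that make a metal chelator (ncbi_8258799, -5.39 ± 0.58, and ncbi_8261713, -5.36 ± 1.29) and expansin-A8 (ncbi_8259547, -5.38 ± 1.05). Cytochrome P450 89A2-like (ncbi_8284293) was also among them, with 224 counts over the 3 control libraries and 2 over the 3 PEG libraries.

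Among 31 enzymes that remove reactive oxygen, 6 were higher and 2 lower at 3 days, and the same numbers held when adjusted over the list alone. The list took in superoxide dismutases, catalases, enzymes of the ascorbate-glutathione cycle, glutathione peroxidases and peroxiredoxins. 1-Cys peroxiredoxin (ncbi_8262608) rose by 3.34 ± 0.86 and glutathione peroxidase (ncbi_8264294) by 2.80 ± 0.43, from 17.6 ± 8.16 to 91.9 ± 11.6 FPKM. Catalase isozyme 1 (ncbi_8273613, named after its values were seen) rose by 2.09 ± 0.31, while catalase isozyme 2 (ncbi_107261240) fell by 2.17 and a monodehydroascorbate reductase-like gene (ncbi_8258892) by 0.76. The list as a whole had a median of 0.39 and a camera adjusted p of 0.0329, but adjusted p = 0.544 with an estimated correlation, and its median was -0.05 when libraries were scaled by their totals, with 4 higher and 4 lower. Its camera adjusted p was 0.121 without the 3-day control library 2 and 0.163 without PEG library 1. Class III peroxidases, which act in the cell wall, had 0 higher and 6 lower of 52 (0 and 5 adjusted over the list alone). Their median was -0.84, with camera adjusted p = 0.0464, or adjusted p = 0.544 with an estimated correlation. Peroxidase 21 (ncbi_8284550) went from 465 ± 207 to 54.0 ± 23.9 FPKM (-2.66 ± 0.44), and peroxidase 10-like (ncbi_8283272) changed by -3.27 ± 0.55. Without control library 1 the median of these peroxidases was -0.24 (adjusted p 0.116), and without PEG library 2 it was -0.61 (adjusted p 0.24). The call also ended without a filter (median -0.62, adjusted p 0.0801), with a replicate block (median -0.76, adjusted p 0.0513) and with library totals (median -1.30, adjusted p 0.255), a scaling under which the median of all genes was -0.523 in place of -0.082. Glutathione S-transferases split into 14 higher and 3 lower of 43 (14 and 5 adjusted over the list alone), with parC (ncbi_8274525) at 4.25 ± 1.01, and their camera adjusted p was 0.0673. Library totals gave 11 higher and 9 lower, with the median going from 0.23 to -0.20. Of 6 NADPH oxidases, which make superoxide at the plasma membrane, 2 were lower (4 adjusted over the list alone), respiratory burst oxidase E (ncbi_8259058, -2.19 ± 0.50) and C-like (ncbi_8275460, -1.23 ± 0.33).

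Abscisic acid signalling genes had 5 higher and 1 lower of 25 (7 and 1 adjusted over the list alone), a median of 0.41 and camera adjusted p = 0.048, or adjusted p = 0.544 with an estimated correlation. Protein phosphatase 2C 56-like (ncbi_8268292) rose by 2.04 ± 0.36 and the ABRE-binding factor ABSCISIC ACID-INSENSITIVE 5-like protein 7 (ncbi_8286238) by 1.78 ± 0.30, while the kinase SRK2A (ncbi_8267034) fell by 0.77. The median of this list was -0.03 under scaling by library totals, with 3 higher and 4 lower (adjusted p 0.091), and its adjusted p was 0.0522 with a replicate block. It was 0.136 without control library 1 (median 0.24) and 0.0554 without control library 3 (median 0.38). Without PEG library 2 the adjusted p was 0.0811 (median 0.31), and without PEG library 3 it was 0.0605 (median 0.44). Of 13 genes of abscisic acid metabolism 3 were higher and none lower (6 higher and 2 lower adjusted over the list alone), against 2 higher and 3 lower with library totals. They were a pair of zeaxanthin epoxidase-like genes, which act early in the pathway (ncbi_8267996, 4.08 ± 0.72, and ncbi_8267999, 3.09 ± 0.66), and the 9-cis-epoxycarotenoid dioxygenase NCED5 (ncbi_8264093, 1.70 ± 0.46), of the family that cleaves the carotenoid precursor, named after its value was seen. Raffinose, galactinol and trehalose genes had 7 higher and 2 lower of 24 (7 and 3 adjusted over the list alone), with trehalose-phosphate synthase 11 (ncbi_8270664, 2.53 ± 0.65) and 9 (ncbi_8289035, 2.33 ± 0.48) higher and synthase 1-like (ncbi_8269054, -1.75 ± 0.29) lower. In proline metabolism, pyrroline-5-carboxylate reductase (ncbi_8286644) rose by 0.94 ± 0.33, the only call among 3 genes tested. The search for LEA proteins and dehydrins also caught 7 GEM-like proteins, which are not LEA proteins. Without them 3 of 14 genes were higher and none lower, with a median of 0.45 and camera adjusted p = 0.159. Heat shock proteins and factors had 13 higher and 8 lower of 71 (14 and 9 adjusted over the list alone), but 10 higher and 17 lower with library totals, where their median was -0.20 in place of 0.23. Autophagy genes had 10 higher and 0 lower of 24 (10 and 1 adjusted over the list alone), including a pair of Autophagy-related 2 genes (ncbi_8271821, 1.64 ± 0.51, and ncbi_8272337, 1.53 ± 0.45). Their median was 0.74, with camera adjusted p = 0.000513, or adjusted p = 0.544 with an estimated correlation, and library totals left 2 higher and 1 lower. Genes of the low-oxygen response had 4 higher and 1 lower of 14 (5 and 1 adjusted over the list alone). Pyruvate decarboxylase 1 (ncbi_8283141), the entry to ethanol fermentation, went from 399 ± 188 to 1770 ± 639 FPKM (2.60 ± 0.43). That list had a median of 0.60 and camera adjusted p = 0.0143, against adjusted p = 0.457 with an estimated correlation. Without PEG library 1 its median was 0.30 and its camera adjusted p 0.0692.

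Transporters of nitrate, ammonium, phosphate and sulfate had 2 higher and 19 lower of 52 at 3 days (2 and 20 adjusted over the list alone), a median of -1.0 and camera adjusted p = 6.78e-05. This was the only list at 3 days whose call held with an estimated correlation (adjusted p = 0.0446 with an estimated correlation). NRT1/PTR family 2.7-like (ncbi_8289754) went the other way, at 2.93 ± 0.58, as did a phosphate transporter (ncbi_8275509) at 3.84 ± 0.38. Potassium and sodium transport genes had 1 higher and 10 lower of 36 (1 and 11 adjusted over the list alone), led by potassium transporter 5-like (ncbi_8285713, -3.23 ± 0.46), with a median of -0.43 and camera adjusted p = 0.00836, or adjusted p = 0.277 with an estimated correlation. Of 24 aquaporins, the water channels, 4 were lower and none higher (3 and none adjusted over the list alone), and PIP2-8-like (ncbi_8278125) went from 33.9 ± 12.3 to 1.19 ± 0.705 FPKM (-4.37 ± 0.54). Pectin-modifying enzymes had 3 higher and 13 lower of 68 (6 and 14 adjusted over the list alone). They had a median of -1.04 and camera adjusted p = 0.0158, or adjusted p = 0.572 with an estimated correlation. Their median was -0.07 without control library 1 (adjusted p 0.136) and -0.81 without PEG library 2 (adjusted p 0.0902). The call also ended with library totals (median -1.49, adjusted p 0.1) and without a filter (median -0.50, adjusted p 0.0506). Phenylpropanoid and lignin genes had 7 higher and 18 lower of 72 (7 and 21 adjusted over the list alone). They had a median of -0.74 and camera adjusted p = 0.0221, or adjusted p = 0.544 with an estimated correlation and 0.119 without PEG library 2 (median -0.57). With library totals the median was -1.18 and the adjusted p 0.0904. A laccase-12-like gene (ncbi_8272100), of enzymes that couple lignin units, changed by -4.56 ± 0.97. Genes of xylem secondary walls had 1 higher and 6 lower of 23 (1 and 7 adjusted over the list alone), with a median of -0.94 and camera adjusted p = 0.00861. Phloem genes had 0 higher and 5 lower of 12 (0 and 6 adjusted over the list alone), with a median of -1.41 and camera adjusted p = 0.0158. Both xylem (adjusted p = 0.544 with an estimated correlation) and phloem (adjusted p = 0.277 with an estimated correlation) lost their calls that way. Sieve element occlusion B-like (ncbi_8260350), a phloem-sealing protein, changed by -2.60 ± 0.65. Casparian strip genes moved both ways, 4 higher and 5 lower of 22 (4 and 5 adjusted over the list alone), and CASP-like 1D1 (ncbi_8262392) reached 1560 ± 216 FPKM from 415 ± 115 (2.34 ± 0.30).

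Regulators and hormone genes moved in both directions at 3 days. NAC factors had 10 higher and 4 lower of 38 (10 and 4 adjusted over the list alone), among them NAC 72 (ncbi_8263571, 3.42 ± 0.68), a dehydration-induced factor. AP2/ERF factors had 10 higher and 5 lower of 70 (10 and 5 adjusted over the list alone), with ERF098 (ncbi_8259178) at 4.56 ± 0.48 and the growth regulator ANT (ncbi_8265250) at -3.44 ± 0.66. MYB factors had 9 higher and 6 lower of 75 (9 and 6 adjusted over the list alone). The WRKY family had 5 higher and 2 lower of 54 (2 and 2 adjusted over the list alone). AP2/ERF, MYB and WRKY factors each had a smaller share called than the 23.1% of all tested genes. The balance of all 4 families turned with library totals, to 4 higher and 7 lower NAC, 6 and 11 AP2/ERF, 6 and 15 MYB and 2 and 5 WRKY factors. The bHLH factors fell more often than they rose, 14 against 4 of 66 (16 and 4 adjusted over the list alone), with a median of -0.36 and camera adjusted p = 0.0247, or adjusted p = 0.277 with an estimated correlation. Library totals gave 2 higher and 26 lower, with a median of -0.81 and an adjusted p of 0.057. 1-Aminocyclopropane-1-carboxylate synthase 1 (ncbi_8286682), which makes the ethylene precursor, rose from 1.15 ± 0.883 to 26.9 ± 10.3 FPKM (4.97 ± 0.82). Gibberellin 2 oxidase 1 (ncbi_8286217, 3.16 ± 0.96), which inactivates gibberellin, rose while the synthetic enzyme gibberellin 20 oxidase 1 (ncbi_8258329, -3.37 ± 0.58) fell. The auxin efflux carrier component 1c (ncbi_8283128) changed by -2.34 ± 0.29, and the jasmonate repressors TIFY 5A-like (ncbi_8264090 and ncbi_8264089) by 3.32 ± 0.80 and 2.61 ± 0.51.

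Photosynthesis genes, fixed beforehand as markers of shoot tissue, had 9 higher and 0 lower of 38 at 3 days (11 and 0 adjusted over the list alone), with a median of 0.84 and camera adjusted p = 0.000513, or adjusted p = 0.544 with an estimated correlation. Histones had 11 higher and 0 lower of 30 (13 and 0 adjusted over the list alone). Their median was 0.51 (camera adjusted p = 0.00119, or adjusted p = 0.277 with an estimated correlation). Cytosolic ribosomal proteins had 27 higher and 1 lower of 158 (16 and 0 adjusted over the list alone). Their median was 0.62 (camera adjusted p = 7.21e-08, or adjusted p = 0.576 with an estimated correlation). Gene length moved with the same comparison. The shortest 10% of genes, with a median length of 684 bases, had a median log2 change of 0.58, and the longest 10%, at 3825 bases, one of -0.51. With that trend taken out the median of the histones was 0.07 (camera adjusted p 0.235) and that of the ribosomal proteins 0.26 (camera adjusted p 0.0545). The enzymes that remove reactive oxygen had 0.15 (camera adjusted p 0.187) and potassium and sodium transport -0.02 (camera adjusted p 0.0789). Scaling by library totals moved the median of all genes from -0.082 to -0.523 and the split of calls from 1883 higher and 1829 lower to 912 and 4157. Limma on log2 FPKM, which is also scaled by library totals, gave 967 and 3772. Under library totals photosynthesis genes had 3 higher and 0 lower, histones 5 and 2, and ribosomal proteins 8 and 4. The count of 3712 calls was 1900 without control library 1 and 2107 without PEG library 2, and 1285 when only the 6 libraries of that day were fitted; 56 of 141 named genes lost their call without at least 1 library.

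**Figure D1:**
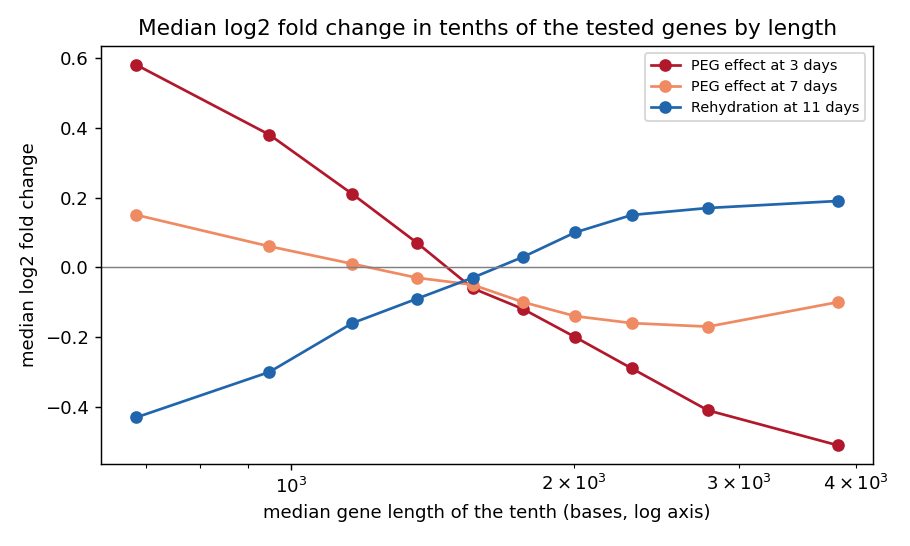
Median log2 fold change in 10 equal bins of the tested genes ordered by length, against the median length of each bin in bases on a log axis, for PEG at 3 days, PEG at 7 days and rehydration at 11 days. From the shortest to the longest bin the line falls from 0.58 to -0.51 at 3 days and from 0.15 to -0.10 at 7 days, and rises from -0.43 to 0.19 after rehydration.

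After 7 days in PEG the roots differed from their controls in fewer genes, and the group that stood out was photosynthesis. Of 38 such genes, 26 were higher and none lower (30 and none adjusted over the list alone), with a median of 2.23 and camera adjusted p = 2.22e-32, or adjusted p = 0.0761 with an estimated correlation. Photosystem I subunit VI-2 (ncbi_8274477) went from 10.2 ± 5.56 to 93.2 ± 15.0 FPKM (3.46 ± 0.59), and a weakly expressed Rubisco activase gene (ncbi_8274858) from 0.717 to 5.89 FPKM (3.34 ± 0.72). The more abundant Rubisco activase 2 (ncbi_8276600) was not called, at 34.3 ± 16.7 against 21.9 ± 15.7 FPKM (0.97 ± 0.70), nor were Rubisco small chain genes (ncbi_8271820, 2.31 ± 0.63, edgeR adjusted p 0.0501, and ncbi_8260287, 0.35 ± 0.37), all looked up here after the values were seen. Chlorophyll a-b binding protein of LHCII type 1 (ncbi_8264152, named after its values were seen) went from 158 ± 87.8 to 901 ± 185 FPKM. The 3 PEG libraries lay 2.60, 2.17 and 2.06 above the mean of the 7-day controls in the median of these genes, and every untreated library lay between -0.54 and 0.57 of its own day's mean.

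**Figure D2:**
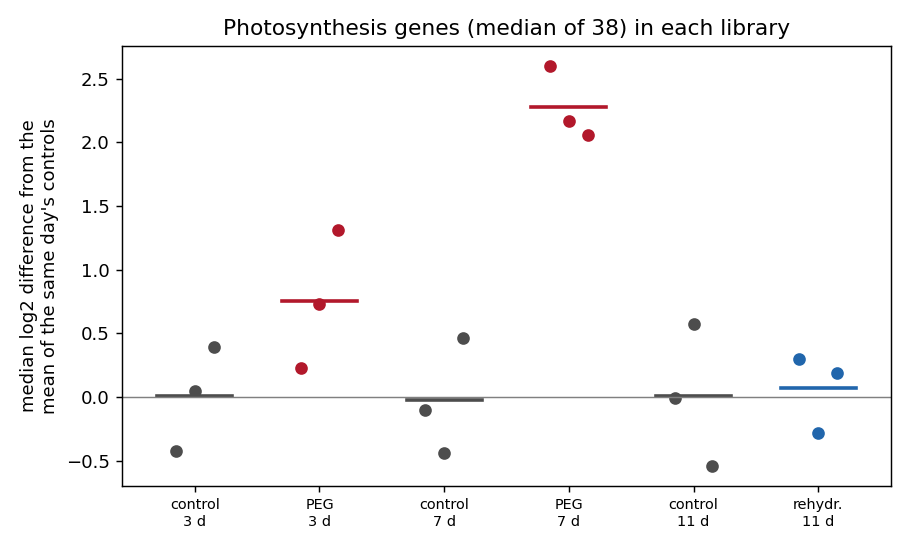
Median over 38 photosynthesis genes of the log2 difference of each library (points) from the mean of the same day's controls, with the group mean as a line. The PEG libraries of day 7 lie at 2.06 to 2.60, those of day 3 at 0.23 to 1.31, and the rehydrated libraries at -0.28 to 0.30.

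In all, 417 genes were higher and 235 lower at 7 days at an edgeR adjusted p below 0.05, together 4.1% of the genes tested. Of these 652, 575 changed at least 2-fold. The largest increases were shared in part with day 3. The alpha-amylase/subtilisin inhibitor-like gene (ncbi_8276905) stood at 5.52 ± 0.98, chitinase 3 (ncbi_8282608) at 3.97 ± 1.00, the flavonoid enzyme naringenin,2-oxoglutarate 3-dioxygenase-like (ncbi_8270763) at 3.81 ± 0.84, secoisolariciresinol dehydrogenase-like (ncbi_8286003) at 3.68 ± 0.73 and PLANT CADMIUM RESISTANCE 9-like (ncbi_8269711) at 3.62 ± 0.74. A lipid-transfer protein-like gene (XLOC_014486, 4.37 ± 1.09), the zinc finger family protein (ncbi_8269145, 3.88 ± 0.95) and a STIG1-like gene (ncbi_8277988, 3.66 ± 0.99) completed them. Among the largest decreases were 5'-adenylylsulfate reductase 1 (XLOC_010482, -4.05 ± 0.70), a central enzyme of sulfate reduction, SULFUR DEFICIENCY-INDUCED 1 (ncbi_8280694, -3.65 ± 0.40, from 8.19 ± 2.28 to 0.540 ± 0.142 FPKM), homocysteine S-methyltransferase 1 (ncbi_8285786, -3.45 ± 0.55) and S-adenosylmethionine synthetase (ncbi_8261334, -3.23 ± 0.59). A CASP-like protein (ncbi_8271450, -4.06 ± 0.50), inorganic pyrophosphatase 1-like (ncbi_8266982, -3.83 ± 0.73), a tropinone reductase homolog (ncbi_8261980, -3.73 ± 0.62) and GEM-like protein 4 (ncbi_8260722, -3.73 ± 0.97) made up the rest.

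Enzymes that remove reactive oxygen had 4 higher and 0 lower of 31 at 7 days (9 and 0 adjusted over the list alone), with 1-Cys peroxiredoxin (ncbi_8262608) at 3.29 ± 0.85, a chloroplast glutathione peroxidase (ncbi_8274172) at 1.32 ± 0.26 and catalase isozyme 1 (ncbi_8273613) at 1.11 ± 0.30, and a camera adjusted p of 0.0551. With library totals 1 was higher and 0 lower, and the median was 0.18 in place of 0.44. Class III peroxidases had 0 higher and 1 lower of 52 (0 and 1 adjusted over the list alone), with a median of -0.95 and camera adjusted p = 0.00727, or adjusted p = 0.698 with an estimated correlation, and with library totals a median of -1.14 and an adjusted p of 0.0641. Peroxidase 47 (ncbi_8285000) was the member called, at -1.34 ± 0.29. Nutrient transporters had 0 higher and 6 lower of 52 (1 and 10 adjusted over the list alone), with a median of -0.60 and camera adjusted p = 0.00107, or adjusted p = 0.0761 with an estimated correlation. The named members carry sulfate, the low affinity sulfate transporter 3 (ncbi_8265600, -3.10 ± 0.74) and sulfate transporter 1.3-like (ncbi_8263028, -2.64 ± 0.56). Phenylpropanoid genes had 0 higher and 5 lower of 72 (2 and 9 adjusted over the list alone), with 4-coumarate--CoA ligase 1-like (ncbi_8280301) at -2.27 ± 0.47. Their median was -0.50 (camera adjusted p = 0.00176, or adjusted p = 0.698 with an estimated correlation). Pectin-modifying enzymes had 0 higher and 3 lower of 68 (1 and 4 adjusted over the list alone). Their median was -0.92 (camera adjusted p = 0.00157, or adjusted p = 0.698 with an estimated correlation). Xylem genes had 0 higher and 2 lower of 23 (0 and 3 adjusted over the list alone). Their median was -1.56 (camera adjusted p = 1.46e-05, or adjusted p = 0.698 with an estimated correlation). Phloem genes had 0 higher and 2 lower of 12 (0 and 6 adjusted over the list alone). They had a median of -1.42 (camera adjusted p = 0.000763, or adjusted p = 0.0761 with an estimated correlation). Autophagy genes had 1 higher and 0 lower of 24 (3 and 0 adjusted over the list alone). They had a median of 0.36 (camera adjusted p = 0.00428, or adjusted p = 0.698 with an estimated correlation). Without the 7-day control library 2 their median was 0.22 and their camera adjusted p 0.0509. Aquaporin TIP1-3 (ncbi_8275924) was the only water channel called of 24, at -2.16 ± 0.51 and 142 ± 1.75 FPKM against 763 ± 458. Adjusted over the list alone 1 was higher and 1 lower.

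The 7-day count leaned on single libraries. It was 80 without control library 1, 47 without control library 2, 56 without PEG library 1 and 125 without PEG library 3, against 652 with all, and 57 of 61 genes kept for naming lost their call in at least 1 of these fits. The count was 1688 with DESeq2 and 170 when only the 6 libraries of that day were fitted. Scaling by library totals moved the median of all genes from -0.059 to -0.307 and the split to 188 higher and 450 lower, against 417 and 235. Limma on log2 FPKM, which is also scaled by library totals, gave 285 and 564.

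The effects of PEG at both times pointed the same way for most genes called at either. Of the 417 genes higher at 7 days, 405 also had a positive fold change at 3 days, with a median of 1.35 there, and 218 of the 235 lower ones a negative fold change. Called at both times were 292 higher genes, where independent lists would share 48.8, and 142 lower genes, where they would share 26.7 (Fisher's exact test with both tails, p = 1.74e-178 and 3.09e-74). Genes are not independent of each other, and 3 genes were called in opposite directions. DESeq2 gave 660 higher, 353 lower and 13 opposite. Across genes, which are not independent replicates, the fold changes of both times had a Pearson correlation of 0.609 and a Spearman correlation of 0.642. The shared higher and lower genes were 38 and 22 without 7-day control library 1, 20 and 16 without its library 2, 33 and 8 without 7-day PEG library 1, 66 and 20 without its library 3, and 161 and 79 without 3-day PEG library 3. The lower ones were 93 without 3-day control library 3 and 218 without 3-day PEG library 1.

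Whether the effect of PEG differed between 7 and 3 days was tested as an interaction, and 38 genes passed, 22 with a more positive and 16 with a more negative effect at 7 days. Of these, 37 were called at 3 days and 5 at 7 days, where the test subtracts the 3-day effect and so favours genes with a large one. DESeq2 passed 249 genes, a fit with a replicate block 21 and a fit of the compared libraries alone 19. The nitrate transporter 2.1-like gene (ncbi_8275209) went from -6.24 at 3 days to a fitted -1.26 ± 0.48 at 7 days, a difference of 4.98 ± 0.78, and aquaporin PIP2-8-like (ncbi_8278125) from -4.37 to -0.41, a difference of 3.96 ± 0.68. In the other direction, the cinnamyl-alcohol dehydrogenase family protein (ncbi_8260964) stood at 240 ± 24.2 FPKM in PEG roots at 3 days and at 12.7 ± 4.80 at 7 days, a difference of -6.13 ± 0.81, and a calmodulin gene (ncbi_8258834), a calcium sensor, differed by -4.79 ± 0.65. A phosphate transporter (ncbi_8275509) that rose by 3.84 ± 0.38 at 3 days had 0.07 at 7 days, a difference of -3.77 ± 0.52. Photosynthesis genes had a larger effect at 7 than at 3 days (median difference 1.41, camera adjusted p = 2.19e-10, or adjusted p = 0.492 with an estimated correlation). With 1 library left out the count of 38 was 20 or 16 without 3-day control libraries 1 or 3, 14 or 25 without 7-day control libraries 1 or 2, and 21, 17 or 19 without 7-day PEG libraries 1, 2 or 3.

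**Figure D3:**
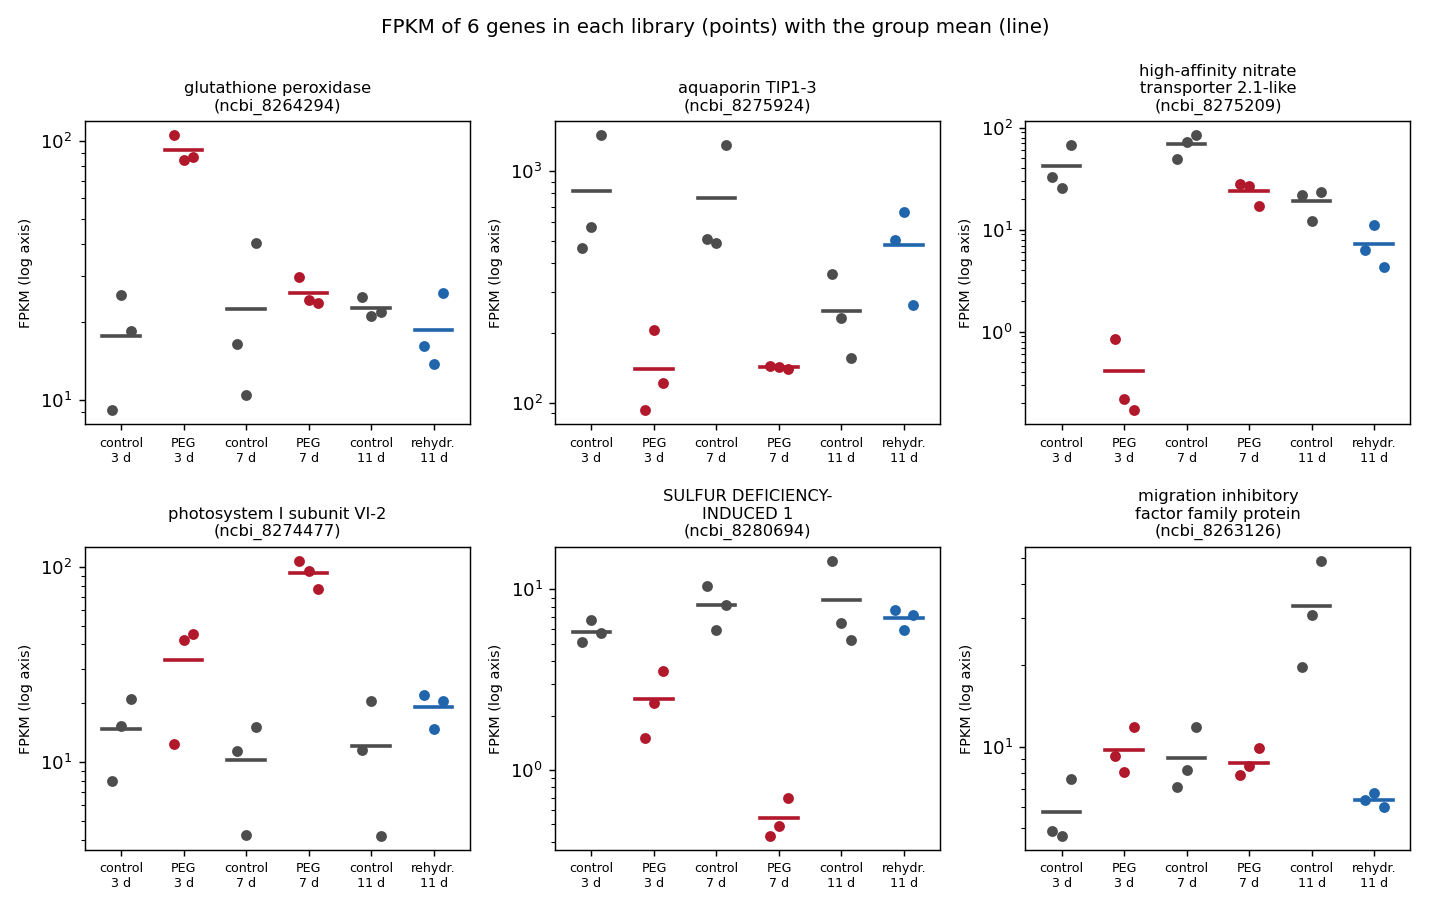
FPKM of 6 genes in each library (points, log axis) with the mean of each group (line), for untreated, PEG-treated and rehydrated (rehydr.) roots. Glutathione peroxidase was higher in PEG roots at 3 days (91.9 against 17.6), the nitrate transporter fell to 0.413 at 3 days, the photosystem I gene reached 93.2 and SULFUR DEFICIENCY-INDUCED 1 fell to 0.540 at 7 days, and the migration inhibitory factor gene was highest in the 11-day controls (33.1).

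Rehydrated roots, 4 days after PEG was taken away, differed from untreated roots of the same age in 2 called genes of 16085. Cytochrome P450 71A26-like (ncbi_8278263) was higher, at 6.97 ± 0.826 against 2.12 ± 0.873 FPKM (1.67 ± 0.25, edgeR adjusted p 0.0404), and a macrophage migration inhibitory factor family protein (ncbi_8263126) was lower, at 6.37 ± 0.365 against 33.1 ± 14.5 FPKM (-2.49 ± 0.37, edgeR adjusted p 0.0404). In both cases the untreated 11-day group stood apart from the other untreated roots, at 8.04 ± 0.557 FPKM at 3 days for the cytochrome and 5.73 ± 1.64 for the other gene. The genes that PEG had raised at 7 days had a median log2 difference of -0.15 after rehydration, and those it had lowered a median of 0.00. The genes raised at 3 days had a median of -0.26 after rehydration, with 32.6% of the same sign, and those lowered at 3 days one of 0.16, with 33% of the same sign. Across genes, which are not independent replicates, the fold changes at 3 days and after rehydration had a Spearman correlation of -0.267. Fold changes also followed gene length in opposite senses, with Spearman correlations of -0.319 at 3 days and 0.365 after rehydration. These shares and the correlation of -0.267 were not computed without that trend, so its part in them cannot be told here. Of the 652 genes called at 7 days, 0 were called after rehydration in the same direction (DESeq2 called 7 such genes, and 1564 genes had an unadjusted p below 0.05 after rehydration in edgeR). Photosynthesis genes had a median of -0.01 and a camera adjusted p of 0.778.

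No member of any of the 41 lists was called after rehydration when adjusted over all genes, and adjusted over the list alone 1 expansin-type gene, 1 low-oxygen gene and 2 pectin-modifying genes were lower and 1 pectin-modifying gene was higher. Some lists still shifted by small amounts. WRKY factors had a median of 0.31 (camera adjusted p = 0.00095, or adjusted p = 0.9 with an estimated correlation), and genes of sugar transport and breakdown one of 0.30 (camera adjusted p = 0.00654, or adjusted p = 0.882 with an estimated correlation). Glutathione S-transferases had a median of -0.47 (camera adjusted p = 0.00102, or adjusted p = 0.882 with an estimated correlation), and ribosomal proteins one of -0.43 (camera adjusted p = 1.13e-10, or adjusted p = 0.9 with an estimated correlation). With the length trend removed these last medians were -0.27 (camera adjusted p 0.286) and -0.10 (camera adjusted p 0.131), and that of the sugar genes 0.23 (camera adjusted p 0.0763). The WRKY median was 0.03 without rehydrated library 3 (adjusted p 0.152), that of the transferases -0.35 without rehydrated library 2 (adjusted p 0.0856), and that of the sugar genes 0.24 without control library 1 (adjusted p 0.0793). The count of 2 genes was 0 without 11-day control library 2 or 3 or any 1 of the 3 rehydrated libraries, 3 without control library 1, 58 with DESeq2, 4 with limma, 1 with library totals, and 0 without a filter or with the compared libraries alone.

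The difference from control moved between 7 days in PEG and rehydration for 108 genes, 14 upward and 94 downward. Of these, 86 were called at 7 days and moved back, which the test favours because it subtracts the 7-day effect. DESeq2 gave 942 genes, limma 50 and 23 with its offsets of 1 and 0.1, and the compared libraries alone 436. The weakly expressed Rubisco activase gene (ncbi_8274858) went from 3.34 to -1.83, a difference of -5.17 ± 1.02. It stood at 0.587 ± 0.188 FPKM in rehydrated roots, 2.03 ± 1.85 in 11-day controls and 0.717 in 7-day controls. The more abundant Rubisco activase 2 (ncbi_8276600) had 0.97 at 7 days and 0.66 after rehydration, neither called. The photosynthesis list had 6 genes lower and 0 higher (27 and 0 adjusted over the list alone). Its median was -2.15 (camera adjusted p = 3.65e-19, or adjusted p = 0.253 with an estimated correlation). None of its genes was called with library totals (median -1.79) or with the length trend removed (median -1.90). PLANT CADMIUM RESISTANCE 9-like (ncbi_8269711, -4.63 ± 1.02), a prolyl 4-hydroxylase subunit (ncbi_8272249, -4.20 ± 0.80) and a sulfite exporter family protein (ncbi_8274876, -4.00 ± 0.86) also moved down. SULFUR DEFICIENCY-INDUCED 1 (ncbi_8280694) moved up by 3.31 ± 0.52, from -3.65 at 7 days to -0.34, and the tropinone reductase homolog (ncbi_8261980) by 4.43 ± 0.82. Xylem (median 1.74, camera adjusted p = 9.78e-05, or adjusted p = 0.737 with an estimated correlation) and phloem genes (median 2.08, camera adjusted p = 0.003, or adjusted p = 0.253 with an estimated correlation) moved up as lists. No gene of either was called when adjusted over all genes, and 1 xylem and 6 phloem genes were higher and 1 phloem gene lower adjusted over the list alone. The subtraction also favours lists shifted at 7 days, as photosynthesis, xylem and phloem were (medians 2.23, -1.56 and -1.42). Both fasciclin-like arabinogalactan protein 12 genes of the xylem list (ncbi_8279895 and ncbi_8279890) had 0 counts in rehydrated roots and in 11-day controls, so they did not return. Scaling by library totals, which moved the median of all genes from 0.04 to 0.352, gave 10 genes up and 10 down in place of 14 and 94, and removing the length trend 3 up and 2 down. With 1 library left out the count was 4, 6 or 433 without 7-day control libraries 1, 2 or 3, 209, 3 or 20 without 11-day control libraries 1, 2 or 3, 3, 213 or 8 without 7-day PEG libraries 1, 2 or 3, and 3, 3 or 8 without rehydrated libraries 1, 2 or 3.

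Few genes were called between untreated roots of different age. Between 3 and 7 days edgeR called 0 genes, with 179 at an unadjusted p below 0.05, and DESeq2 and limma also called 0. Between 3 and 11 days 1 gene was higher and 4 were lower, all named here after their values were seen. The migration inhibitory factor family protein (ncbi_8263126) rose by 2.52 ± 0.37. Oleosin 1-like (ncbi_8264538, -2.48 ± 0.29), a coat protein of oil bodies, MIZU-KUSSEI 1 (ncbi_8269965, -1.47 ± 0.24), known from the growth of roots toward water, the sphingolipid enzyme TSC10A-like (ncbi_8271593, -1.18 ± 0.18) and cytochrome P450 71A26-like (ncbi_8278263, from 8.04 ± 0.557 to 2.12 ± 0.873 FPKM) fell. The count of 5 was 61 with DESeq2, 11 and 8 with limma at its offsets of 1 and 0.1, and 0 with the compared libraries alone. It was 2, 2 or 3 without 3-day control libraries 1, 2 or 3, and 1 or 3 without 11-day control libraries 2 or 3.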

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

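The interaction tests, their list tests, the estimated correlations and the fits with 1 library left out were planned, as were the tests of shoot tissue, a few gene families and wider spread; the other tests of explanations, the exchanges of libraries, library totals and length removal were chosen only after the result was seen.

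Photosynthesis genes were higher in PEG roots at 7 days, with a median of 2.23 over 38 genes, of which 26 were called, and adjusted p = 0.0761 with an estimated correlation for the list. The lowest median with 1 library left out was 2.02, library totals gave 1.95 and length removal 2.15, which argues against a single library, the scaling and gene length as its source. Shoot tissue in the sample could also raise these genes, but only 2 of 21 leaf polarity and stomatal genes were expressed enough to test and their median was 0.00, so leaf tissue and greening of the roots cannot be told apart here. Chlorophyll synthesis genes moved less as a group, with 1 of 13 higher and 0 lower (median 0.42). Of 10 genes caught by a search for photorespiration 1 was higher and 0 lower (median 0.44). That search also caught D-3-phosphoglycerate dehydrogenases, which are not photorespiration enzymes, at -5.28, -1.88 and 0.39, so its median does not stand for photorespiration. The other genes it caught had 0.99, 1, -0.4, 0.5, 1.67, -2 and 2.36. The photorespiration gene called was serine--glyoxylate aminotransferase (ncbi_8286122), at 181 against 43.4 FPKM. Glycine dehydrogenase (ncbi_8275599) stood at 7.76 against 35.0 FPKM but was not called (edgeR adjusted p 0.074). Light reaching the roots during treatment is a hypothesis that the labels leave open, and counts of root and hypocotyl pieces kept in the dark would test it.

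Gene length went with the change at 3 days, with a Spearman correlation of -0.319 across genes, which are not independent replicates, less so at 7 days (-0.13) and in the opposite sense after rehydration (0.365). Without ribosomal, histone, photosynthesis and heat shock genes it was -0.309, so these lists alone did not carry it. They hold too small a share of the tested genes for their removal to move it much. The test therefore cannot decide about other families of short genes. The correlation of level with length was 0.034 to 0.060 in the 3-day PEG libraries, below all 9 untreated libraries (0.085 to 0.225) by at least 0.025, while the 7-day PEG libraries (0.077 to 0.111) overlapped them and the rehydrated libraries (0.209 to 0.256) lay above their own controls (0.085 to 0.208). The gap is that of 1 group, whose plants and libraries were both its own, so a change in the plant and a difference in RNA quality or library preparation cannot be told apart. Which of these it was, and why the sense turned after rehydration, stays open, and RNA integrity values, not used here, would tell.

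Fewer genes were called at 7 days (652) than at 3 days (3712). The highest count with 1 library left out was 824, without 7-day PEG library 2. The same step at 3 days gave 1900 to 3959, so no 7-day fit with 1 library left out reached the lowest 3-day count. Each such fit also has fewer libraries to call genes with. The step therefore cannot decide how much a single library hid. The spread within groups at 7 days was 0.82 of that at 3 days and so was not wider. The fit gives each gene 1 spread for all groups, so this ratio cannot decide what set the counts. Changes were smaller at 7 days, with an SD across genes, corrected for error, of 0.73 times that at 3 days, and this may account for the lower count; the slope planned for this, 0.61, was set aside because it also falls when changes of equal size are imperfectly correlated. What made them smaller, adjustment of the roots or the state of the solution, stays open.

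The effect of PEG differed between 7 and 3 days for 38 genes, and 11 of 100 regroupings of the libraries gave as many. The highest count, 561, came with control libraries 2 of both days exchanged. That regrouping left all PEG libraries in their groups and so kept their difference between days. Such regroupings are not free of the effect, so they cannot decide about chance, which stays open. The median differences of the lists called were -0.33 for glutathione S-transferases, -0.56 for raffinose, galactinol and trehalose synthesis, 1.01 for suberin and wax, -0.27 for histones, -0.54 for ribosomal proteins, 0.58 for nutrient transporters, 0.42 for potassium and sodium transport, -0.25 for pathogenesis-related proteins and 1.41 for photosynthesis. With an estimated correlation none of the 9 kept its call (lowest adjusted p = 0.492 with an estimated correlation). Calls ended without 1 library for glutathione S-transferases (3-day PEG library 3, adjusted p 0.0698), histones (3-day control 2 and 7-day PEG 2, 0.0966 and 0.0753) and suberin (3-day PEG 2 and 7-day PEG 2, 0.0599 and 0.0753). That of the nutrient transporters ended without 3-day control 3, 7-day control 1, 3-day PEG 2, 7-day PEG 2 or 7-day PEG 3 (0.11, 0.0817, 0.124, 0.0753 and 0.0577). That of the raffinose genes ended without 3-day control 1 or 3, 7-day control 1, 3-day PEG 1 or 7-day PEG 3 (0.289, 0.0872, 0.126, 0.153 and 0.0837). That of the pathogenesis-related proteins ended without 3-day control 2 or 3, 7-day control 2, 3-day PEG 1, 7-day PEG 1 or 7-day PEG 3 (0.197, 0.0872, 0.165, 0.925, 0.255 and 0.0577), and their median turned to 0.17 without 3-day PEG library 1. The medians that moved most were those of the raffinose genes (-0.33 without 3-day control 1, -0.13 without 7-day control 1, -0.20 without 3-day PEG 1, -0.37 without 7-day PEG 3), the nutrient transporters (0.30 without 3-day control 3, 0.31 without 7-day PEG 2), histones (-0.15 without 3-day control 2), glutathione S-transferases (-0.22 without 3-day PEG 3) and pathogenesis-related proteins (-0.07 without 7-day control 2). With the length trend removed the calls of glutathione S-transferases (median -0.08, adjusted p 0.397), histones (median 0.00, adjusted p 0.529), pathogenesis-related proteins (median -0.28, adjusted p 0.334) and nutrient transporters (median 0.53, adjusted p 0.0671) ended. Library totals, under which the median of all genes was 0.202, ended those of suberin (median 1.25, adjusted p 0.0785) and nutrient transporters (median 0.77, adjusted p 0.0706), and no filter those of nutrient transporters (median 0.68, adjusted p 0.0593) and pathogenesis-related proteins (median -0.34, adjusted p 0.0602). The last also lost their call with DESeq2 size factors (median -0.29, adjusted p 0.0595) and the replicate block (median -0.23, adjusted p 0.0624).

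The largest differences between 7 and 3 days were 5.32 for cytochrome P450 89A2-like (ncbi_8284293), with 224 and 2 counts in control and PEG roots at 3 days and 184 and 77 at 7 days, 4.98 for the nitrate transporter 2.1-like gene (ncbi_8275209), 4.39 for a G-type lectin receptor kinase (ncbi_8272654), 3.96 for aquaporin PIP2-8-like (ncbi_8278125) and 3.65 for a proton-dependent oligopeptide transport family gene (ncbi_8284629). In the other direction they were -6.13 for the cinnamyl-alcohol dehydrogenase family protein (ncbi_8260964), -5.28 for zeaxanthin epoxidase-like (ncbi_8267996), -4.79 for calmodulin (ncbi_8258834), -4.47 for a short-chain dehydrogenase/reductase family gene (ncbi_8276521) and -3.77 for a phosphate transporter (ncbi_8275509).

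The effect of rehydration differed from that of PEG at 7 days for 108 genes, and 9 of 100 regroupings gave as many. The highest count, 4410, came with 7-day control libraries 2 and 3 and 11-day control libraries 1 and 2 exchanged. It left all PEG and rehydrated libraries in their groups and so kept their difference. Chance stays open here too, since such regroupings cannot decide about it. The median differences of the lists called were 0.69 for class III peroxidases, -0.55 for abscisic acid signalling, 0.68 for phenylpropanoid genes, 0.93 for pectin-modifying enzymes, 1.10 for the cell cycle, -0.53 for histones, -0.38 for ribosomal proteins, -0.58 for autophagy, -2.15 for photosynthesis, 1.74 for xylem and 2.08 for phloem. With an estimated correlation none of the 11 kept its call (lowest adjusted p = 0.253 with an estimated correlation). The call of class III peroxidases ended without 7-day control 2 or 3, 11-day control 1, 7-day PEG 3 or rehydrated 3 (adjusted p 0.0597, 0.0628, 0.0792, 0.0502 and 0.111). Abscisic acid signalling lost its call without 7-day control 2 or 3, 11-day control 2 or 3, 7-day PEG 1 or 3, or rehydrated 2 (0.0543, 0.0626, 0.0516, 0.0612, 0.0771, 0.0502 and 0.146), and phenylpropanoid genes without 11-day control 1 or rehydrated 3 (0.0557 and 0.0633). The cell cycle lost it without 7-day control 2, 11-day control 1, 2 or 3, 7-day PEG 1 or 3, or rehydrated 2 (0.102, 0.0511, 0.07, 0.0512, 0.0668, 0.0502 and 0.0749). Histones lost it without 7-day control 1, 11-day control 3, 7-day PEG 3 or rehydrated 2 (0.0546, 0.0612, 0.0502 and 0.061). The median of the cell cycle was 0.66 without 7-day control 2, and that of class III peroxidases 0.43 without rehydrated 3. With the length trend removed the calls of histones (median -0.20, adjusted p 0.96) and ribosomal proteins (median 0.02, adjusted p 0.931) ended. Library totals, under which the median of all genes was 0.352, ended those of class III peroxidases (median 1.02, adjusted p 0.136), abscisic acid signalling (median -0.21, adjusted p 0.0914), phenylpropanoid genes (median 0.93, adjusted p 0.0502), the cell cycle (median 1.36, adjusted p 0.105) and histones (median -0.20, adjusted p 0.0626), and no filter that of class III peroxidases (median 0.56, adjusted p 0.064).

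The largest differences between rehydration and PEG at 7 days were 4.43 for the tropinone reductase homolog (ncbi_8261980), 3.31 for SULFUR DEFICIENCY-INDUCED 1 (ncbi_8280694), 2.59 for cytochrome P450 71A26-like (ncbi_8278263), 2.45 for a beta-galactosidase-like gene (ncbi_8272545) and 2.13 for a BCS1-B gene (ncbi_8258154), and -5.17 for Rubisco activase (ncbi_8274858), -4.63 for PLANT CADMIUM RESISTANCE 9-like (ncbi_8269711), -4.59 for a cysteine-rich transmembrane gene (XLOC_020621), -4.20 for a prolyl 4-hydroxylase subunit (ncbi_8272249) and -4.00 for a sulfite exporter family protein (ncbi_8274876).

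Exchanging libraries between the 2 groups of a comparison allows only 10 splits, too few for a share under 0.05. The real split had 3712 calls at 3 days (highest other 265), 652 at 7 days (0), 2 after rehydration (0), 5 for controls at 11 against 3 days (0), and 0 for controls at 7 against 3 days (0).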

How the results depend on the processing

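Alternative settings changed the number of calls, and some also changed the balance of higher and lower genes. At 3 days (1883 and 1829) it became 967 and 3772 or 950 and 4048 with the limma offsets of 1 and 0.1, which were planned, and 912 and 4157 with library totals. At 7 days (417 and 235) it became 285 and 564 or 235 and 564 with limma, and 188 and 450 with library totals. For rehydration against 7 days (14 and 94) it became 27 and 23 or 12 and 11 with limma, 10 and 10 with library totals and 3 and 2 with length removal. Reversal was looked for only in the genes named, where none changed sign, and the lists called, where camera kept its direction but 4 medians turned sign. These were, with library totals, those of the enzymes that remove reactive oxygen (-0.05) and of abscisic acid signalling (-0.03) at 3 days, that of pathogenesis-related proteins for 7 against 3 days without 3-day PEG library 1 (0.17), and that of ribosomal proteins for rehydration against 7 days with length removed (0.02). The limma fits used FPKM, which is scaled by library totals without TMM. Limma and library totals are thus not separate evidence on the balance of higher and lower genes. The cause of the other shifts was not tested. For PEG at 3 days (3712 calls) the libraries compared alone gave 1285 and an adjusted p below 0.01 gave 1433, and leaving out 1 library gave 1900 to 3959. For PEG at 7 days (652) DESeq2 gave 1688, the libraries compared alone 170, the stricter p 70, and 1 library less 47 to 824. For rehydration (2) DESeq2 gave 58, no filter 0, limma 4 with either offset, the libraries compared alone 0, library totals 1, the stricter p 0, and 1 library less 0 to 3. For the effect of PEG at 7 against 3 days (38) DESeq2 gave 249, the libraries compared alone 19, the replicate block 21, the stricter p 5, and 1 library less 14 to 46. For rehydration against PEG at 7 days (108) DESeq2 gave 942, limma 50 and 23, the libraries compared alone 436, library totals 20, length removal 5, the stricter p 3, and 1 library less 3 to 433. For controls at 11 against 3 days (5) DESeq2 gave 61, limma 11 and 8, the libraries compared alone 0, and 1 library less 1 to 4; for controls at 7 against 3 days 1 library less left 0 to 0. Genes shared between 3 and 7 days were 660 higher, 353 lower and 13 opposite with DESeq2, against 292, 142 and 3, and ran from 20 to 411, 8 to 218 and 0 to 5 with 1 library less. Genes called at 7 days and after rehydration in the same direction were 7 with DESeq2 and 0 to 0 with 1 library less. With an estimated correlation 1 list stayed called at 3 days and 0 in each other comparison, and 0 KEGG terms in every comparison. Length removal left 1 list for rehydration (of 4) and 5 for 7 against 3 days (of 9), and library totals 6 for rehydration against 7 days (of 11). With 1 library less the called lists were 13 to 18 at 3 days, 9 to 11 at 7 days, 4 to 6 after rehydration, 6 to 11 for 7 against 3 days and 7 to 11 for rehydration against 7 days. Library totals, length removal and the last list settings were chosen after seeing the data. Replicate numbers did not pair libraries across groups, since the residuals of 45 pairs of the same number had a median correlation across genes of -0.02 (lowest -0.55, highest 0.62), against 0.03 for other numbers, so no block was used.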

Other observations

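KEGG terms, tested by camera over 113 terms, add groups that the lists did not hold or held only in part. Those given here are some of the terms called, which were 4 at 3 days, 7 at 7 days and 11 after rehydration. The terms were not tested again with the length trend removed, which ended the call of the ribosomal proteins after rehydration. Starch and sucrose metabolism shares its subject with the list of sugar transport and sucrose or starch breakdown. That list was not called at 7 days. At 3 days other glycan degradation had 0 higher and 7 lower of 22 genes (median -1.33, camera adjusted p = 0.00363, or adjusted p = 0.988 with an estimated correlation), and the spliceosome 27 higher and 4 lower of 156 (median 0.17, camera adjusted p = 0.0397, or adjusted p = 0.988 with an estimated correlation). At 7 days porphyrin and chlorophyll metabolism had 5 higher and 0 lower of 41 (median 0.38, camera adjusted p = 0.000359, or adjusted p = 0.0877 with an estimated correlation), carbon fixation 5 higher and 0 lower of 63 (median 0.21, camera adjusted p = 0.0146, or adjusted p = 0.923 with an estimated correlation), and starch and sucrose metabolism 1 higher and 7 lower of 145 (median -0.53, camera adjusted p = 0.00181, or adjusted p = 0.923 with an estimated correlation). After rehydration valine, leucine and isoleucine degradation had a median of 0.35 over 43 genes (camera adjusted p = 9.32e-05, or adjusted p = 0.812 with an estimated correlation), sulfur metabolism -0.33 over 33 (camera adjusted p = 0.0223, or adjusted p = 0.896 with an estimated correlation) and oxidative phosphorylation -0.26 over 104 (camera adjusted p = 0.00729, or adjusted p = 0.896 with an estimated correlation).

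Among the most abundant transcripts, looked at after the values were seen, the translationally controlled tumor protein gene (ncbi_8278734) rose from 5690 to 12900 FPKM at 7 days (1.43) and an indole-3-acetic acid-induced protein ARG2-like gene (ncbi_8259886) from 3310 to 7620 FPKM (1.45). The early light-induced protein gene (ncbi_8280224), of a family that binds chlorophyll under light stress, rose by 2.95 ± 0.63, and the chlorophyll a-b binding genes CAB-151 (ncbi_8273545) and CP26 (ncbi_8283006) by 2.61 ± 0.41 and 2.20 ± 0.34.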
